A study of Mus musculus with 12 samples.

How the data were processed

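Full-length messenger RNA libraries were made from 100 sorted early thymic progenitors each, per the labels' protocols. The submitters' processing notes name TopHat2 2.0.10, SAMtools 0.1.19 and HTSeq 0.5.4p5 and the mouse build mm10. The values used here are RPKM, reads scaled to transcript length and to library size, which the authors deposited as 1 table of 13016 genes and 12 libraries. Which total the authors divided by and how they chose the genes are not given in the sources used here. Every gene in the table was above 0 in at least 3 libraries. Library columns were matched to samples by the samples' own descriptions, and groups and replicate numbers came from the sample titles.

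The smallest steps between low RPKM values gave the whole reads behind them, for 99.96% of genes within 0.001 of a whole number. These reads totalled 12924981 to 32763597 per library. At 5 to 15 RPKM the counting error alone was 3.54% to 4.94% per library, which covers counting error only, since reads amplified from 100 cells are not independent molecules. Replicate libraries differed by far more than counting noise, with chi-square per degree of freedom between 114 and 559, so none were treated as copies of another.

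Genes with at least 1 RPKM in at least 4 of 12 libraries were tested, 10690 in all. The main test was limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with an intensity trend, all 12 libraries in 1 fit with 9 residual degrees of freedom, and Benjamini-Hochberg adjustment at 0.05. Fold changes are therefore on the log2(RPKM + 1) scale, which understates the change of low genes. Camera with a preset correlation of 0.01 tested 24 gene lists, and was run again with an estimated correlation. Fry, also planned, asked whether a list moved in 1 direction at all, not whether it moved more than other genes. Its adjusted p is given where it passed. Of 430 list symbols 320 were in the table, 4 by an older symbol. Ezh2 and Runx1, and beyond the plan Flt3 and Rag1, also had an exact two-sided permutation test. Gene positions came from GENCODE mouse release 21 on GRCm38, the build that mm10 names, where 12860 symbols were placed.

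Groups, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names Ezh2, Runx1, Flt3 and Rag1. Per comparison it then names the 8 genes up and 8 down with the largest change among called genes with no overlap between groups and a mean of at least 5 RPKM in the higher group, or 3 each way with the smallest p where none passed. Per list it names up to 4 called members, or 1 where none passed. Predicted genes and pseudogenes were skipped, and the text leaves out some names the rule gives. An item that the rule gives is not reported here. The alternatives fixed in advance were other pseudocounts, filters and scalings, a fit without trend, array weights, only the 8 libraries compared, a fold threshold, a replicate term and leaving out each library. Alternatives chosen after seeing the data were voom on the recovered reads in 4 forms, the recovered reads without voom's weights at 6 prior counts, 4 further pseudocounts, removal of each library's gene-length trend, and leaving out control 1, dKO 1 and dKO_Flt3ITD 1 together.

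The steps were tested on simulated data with 200 changed genes. For dKO against control, over 10690 genes, limma recovered 2.99% of genes changed by 1 log2 unit, 53.7% at 2 and 92.4% at 3, and 6.60% of its calls were false. Voom on simulated reads of 10685 genes recovered 0% at 1 log2 unit, 35.8% at 2 and 59.1% at 3, with 1.56% of its calls false. For dKO_Flt3ITD against dKO limma recovered 2.99%, 47.8% and 93.9%, with 2.04% of its calls false. The changed genes were drawn only from genes at about 5 RPKM or more in control, so none was barely detected before its change. These shares therefore do not show how often genes barely detected before the change were recovered, by limma or by voom. The simulated spread was normal on the log scale, as limma assumes. Calculations outside R used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures matplotlib 3.10.9.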

Results

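Early thymic progenitors are the earliest T-lineage cells of the thymus. Their messenger RNA was measured in 12 mouse libraries of 100 sorted cells each, 4 per genotype. Control cells carried floxed Ezh2 and Runx1 alleles without a recombinase. The dKO cells carried the same alleles with the Rag1Cre recombinase. The dKO_Flt3ITD cells carried in addition 1 allele of Flt3 with an internal tandem duplication, an activating mutation of this cytokine receptor that is found in leukaemia. The table held 13016 genes, and the whole reads behind its values totalled 12924981 to 32763597 per library. Libraries of 1 group had a mean correlation of 0.860 over 10690 tested genes, against 0.836 between groups. Control 1 had the lowest mean correlation with the other libraries, 0.786. Nothing in the labels says whether replicates came from separate animals, so p-values measure only the spread between these libraries.

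**Figure D1:**
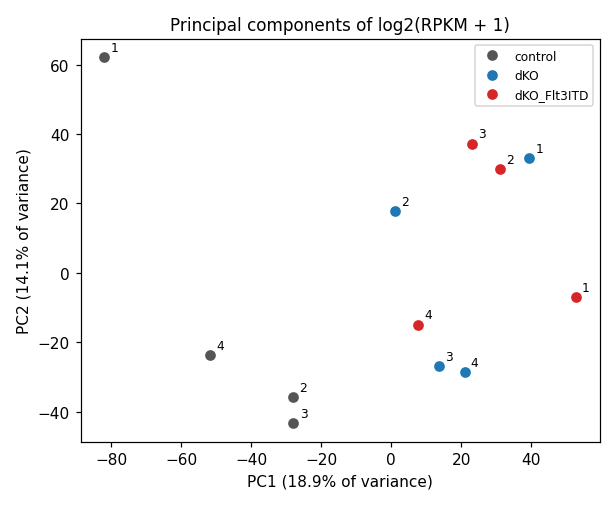
Each point is 1 library on the first and second principal components of log2(RPKM + 1), with the share of variance on each axis and the replicate number beside the point. The 4 control libraries have negative scores on the first component, 18.9% of the variance, and all dKO and dKO_Flt3ITD libraries positive ones. The second component, 14.1% of the variance, divides libraries within each group, with positive and negative scores in all of them.

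Ezh2 encodes the methyltransferase of Polycomb repressive complex and Runx1 a transcription factor of blood cell development. Ezh2 (chromosome 6, 47530139 to 47595341, GRCm38) stood at 39.8 ± 5.83 RPKM (SD, n = 4) in control, 22.6 ± 5.87 in dKO and 16.4 ± 5.59 in dKO_Flt3ITD. All 4 libraries of each mutant group lay below all 4 controls, with an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 allows. In limma over all genes the adjusted p was 0.470 for dKO and 0.0949 for dKO_Flt3ITD, so neither difference passed. Runx1 (chromosome 16, 92601466 to 92826149) was higher, not lower, in the libraries labelled dKO and dKO_Flt3ITD: 21.2 ± 4.57 RPKM in control, 46.4 ± 11.1 in dKO and 47.5 ± 11.8 in dKO_Flt3ITD (SD, n = 4). Its exact permutation p was 0.0286 against control in both, and its limma adjusted p 0.184 and 0.124. A value over the whole gene counts reads outside the deleted part, so it does not check the Runx1 deletion, and directions below rest on the labels. Flt3 (chromosome 5, 147330741 to 147400489) had 78.3 ± 25.7, 29.1 ± 11.5 and 33.2 ± 26.3 RPKM in control, dKO and dKO_Flt3ITD. All 4 dKO libraries lay below all 4 controls for Flt3, with an exact permutation p of 0.0286, while dKO_Flt3ITD against control gave 0.0857. Its limma adjusted p was 0.323 and 0.198. Rag1 (chromosome 2, 101638282 to 101649501) had 0.915 ± 0.771, 2.58 ± 1.62 and 1.62 ± 1.98 RPKM, and neither Flt3 nor Rag1 passed limma in any comparison.

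**Figure D2:**
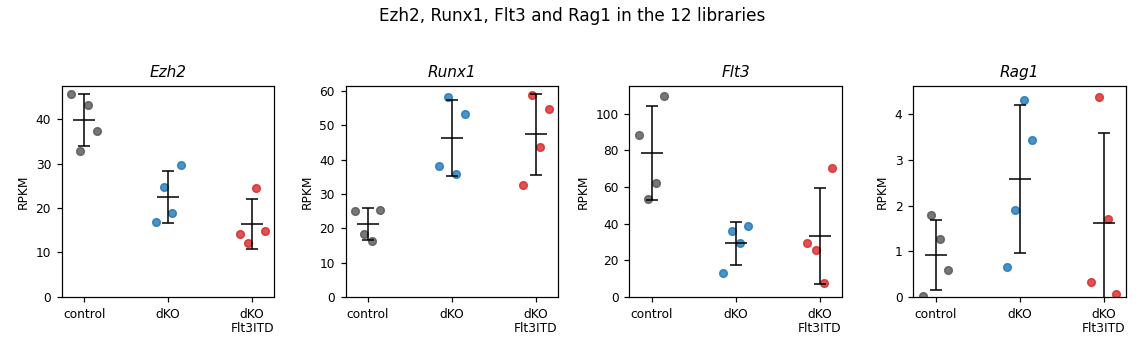
RPKM of Ezh2, Runx1, Flt3 and Rag1 per library (points), with the mean and SD of each group of 4 in black. Ezh2 means are 39.8, 22.6 and 16.4 in control, dKO and dKO_Flt3ITD, and Runx1 means are 21.2, 46.4 and 47.5.

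The comparison of dKO with control addresses loss of both regulators as the labels give it. The largest rises by log2 fold change were in Adamdec1, a metalloprotease gene, from 1.23 ± 1.07 to 1587 ± 542 RPKM (SD, n = 4), and in Rnase12, a secreted ribonuclease gene, with a log2 fold change of 7.97. Rnase10, another gene of that family, rose with a log2 fold change of 5.61. Il4, a cytokine gene of helper T cells and mast cells, rose from 0.0995 ± 0.105 to 95.1 ± 22.4 RPKM, and Efna1, an ephrin ligand, from 0.0685 ± 0.0728 to 67.2 ± 18.4 RPKM. Among the genes that fell were Cd7, from 234 ± 127 to 2.86 ± 3.12 RPKM, Ly6d, from 113 ± 81.0 to 2.06 ± 3.56 RPKM, and Tcf7, which encodes a transcription factor of T-cell specification, from 20.0 ± 17.5 to 0.0267 ± 0.0220 RPKM. In limma these had adjusted p between 1.48e-07 for Il4 and 0.00325 for Cd7, and all 4 dKO libraries lay on 1 side of all 4 controls. The test called 109 of 10690 genes, 84 up and 25 down, with 981 at an unadjusted p under 0.05. Of all tested genes 674, or 6.30%, had no overlap between groups, against the 2.86% that chance gives, and 107 of the called genes were among them.

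That count depended on the test. With voom on the recovered reads, an alternative chosen after seeing the data, 5 genes were called, of which 4 were among the 109. None of the genes named in the previous paragraph passed there, with adjusted p of 0.0747 for Il4, 0.216 for Adamdec1 and Tcf7, and 0.334 for Ly6d. The same reads without voom's weights gave 109 calls, 80 of them shared with the main test. Without dKO 1, dKO 3 or dKO 4 the main test called 67, 63 or 58 genes, and 45 without control 1, dKO 1 and dKO_Flt3ITD 1 together.

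Among gene lists fixed before the data were examined, 2 of 19 tested stem and progenitor genes rose, among them Procr, a surface receptor gene of stem cells, from 3.11 ± 5.47 to 56.9 ± 30.9 RPKM. No member fell, and 5 rose when adjusted over the list alone. Camera called the list up with adjusted p = 0.0148, and adjusted p = 0.198 with an estimated correlation. Fry gave it adjusted p = 0.00174 and called no other list in dKO against control. Of 19 STAT5 targets, Socs2 and Gimap4 rose and none fell, and 7 rose and 2 fell when adjusted over the list alone. Socs2, a feedback inhibitor of cytokine signalling, went from 2.76 ± 2.64 to 69.7 ± 21.04 RPKM. Gimap4 lost its call without dKO 1, dKO 3 or dKO 4, with a highest adjusted p of 0.0685 in limma. The STAT5 list had camera adjusted p = 0.0459, and adjusted p = 0.315 with an estimated correlation. All 20 interferon response genes had a positive log2 fold change, with a median of 1.26, but none passed over all genes and 5 when adjusted over the list alone. Camera gave the interferon list adjusted p = 1.05e-09, and adjusted p = 0.236 with an estimated correlation. Of 18 T-cell specification genes 1 fell, Tcf7, and 17 did not pass, and 10 had positive log2 fold changes. Adjusted over the list alone, 1 rose and 3 fell, and camera gave adjusted p = 0.359. Of 15 lymphoid priming genes none passed, 10 had negative log2 fold changes and 2 fell when adjusted over the list alone. Their camera adjusted p was 0.129, and adjusted p = 0.236 with an estimated correlation. Procr and Gimap4 did not pass without control 1, dKO 1 and dKO_Flt3ITD 1 together, and none of Procr, Socs2, Gimap4 and Tcf7 passed voom.

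Markers of other cells, Polycomb-silenced developmental genes and dissociation stress genes were measured too. All 7 tested macrophage genes had positive log2 fold changes in dKO and none passed, with camera adjusted p = 0.00817, and adjusted p = 0.198 with an estimated correlation. The 6 tested of 35 Polycomb-silenced developmental genes gave camera adjusted p = 0.0200 upward and the 4 natural killer and innate lymphoid genes adjusted p = 0.0148 downward. Both had adjusted p = 0.198 with an estimated correlation, and no member of either passed. In dKO_Flt3ITD against control camera did not call the Polycomb-silenced list, with adjusted p = 0.0790. Of 14 dissociation stress genes 13 had negative log2 fold changes, none passing, with camera adjusted p = 0.00817, and adjusted p = 0.486 with an estimated correlation.

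The comparison of dKO_Flt3ITD with dKO addresses the Flt3 allele on the background labelled double mutant. No gene passed: limma called 0 of 10690 genes, with 824 at an unadjusted p under 0.05, and voom called 0, with 759. The genes named here did not pass. Fos, an immediate early transcription factor gene, had 64.9 ± 24.3 RPKM in dKO and 3.79 ± 5.80 in dKO_Flt3ITD (SD, n = 4; log2 fold change −4.46, SE 0.68, limma adjusted p = 0.0502). Gng11, a G protein subunit gene, had 1.59 ± 1.72 and 19.1 ± 7.43 RPKM, with limma adjusted p = 0.0664. Wfdc18 had 11.05 ± 3.31 RPKM in dKO and was listed at 0 in all 4 dKO_Flt3ITD libraries, with limma adjusted p = 0.0664. Calls appeared when single libraries were left out: 2 without dKO 1, 1 without dKO_Flt3ITD 1, 6 without dKO_Flt3ITD 3 and 1 without dKO_Flt3ITD 4. Fos passed in 3 of those 4 fits, with adjusted p of 0.0325, 0.0361 and 0.000896.

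No list member passed in this comparison. Fry called 2 lists, lymphoid priming and later thymocyte genes, each with adjusted p = 0.0101. All 8 later thymocyte genes had negative log2 fold changes, but camera did not call them, with adjusted p = 0.0925. Of 25 cell cycle genes 22 had negative log2 fold changes, with a median of −0.57. Camera adjusted p was 0.000990, and adjusted p = 0.227 with an estimated correlation. Of 15 lymphoid priming genes 13 were negative, with camera adjusted p = 0.00347, and adjusted p = 0.123 with an estimated correlation. Of 10 ERK output genes 7 were negative and 4 fell when adjusted over the list alone. Among these 4 was Egr1, outside the naming rule, which the dissociation stress list also holds, so the lists are not separate results. The ERK list had camera adjusted p = 0.00265, and adjusted p = 0.173 with an estimated correlation. The 18 T-cell specification genes had adjusted p = 0.0279 and 14 dissociation stress genes adjusted p = 0.00347, both downward, and adjusted p = 0.262 and 0.648 with an estimated correlation.

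The comparison of dKO_Flt3ITD with control takes both changes together. Il4 rose to 139 ± 93.3 RPKM, Adamdec1 to 547 ± 569 and Socs2 to 110 ± 58.1 (SD, n = 4). Serpina3f, a serine protease inhibitor gene, rose from 2.57 ± 2.27 to 104 ± 47.2 RPKM, and Ccl5, a chemokine gene, from 7.58 ± 5.99 to 501 ± 693 RPKM. Dntt, the terminal transferase of antigen receptor joining, fell from 946 ± 411 to 27.7 ± 41.9 RPKM, and Lck, a kinase of T-cell receptor signalling, from 244 ± 111 to 28.0 ± 15.3 RPKM. Fos fell from 141 ± 102 to 3.79 ± 5.80 RPKM, and Cox6a2, a cytochrome oxidase subunit gene, had 24.0 ± 5.27 RPKM in control and was listed at 0 in all 4 dKO_Flt3ITD libraries. All 4 dKO_Flt3ITD libraries lay on 1 side of all 4 controls for each of these genes, and limma adjusted p ran from 5.89e-08 for Il4 to 0.00287 for Ccl5.

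**Figure D3:**
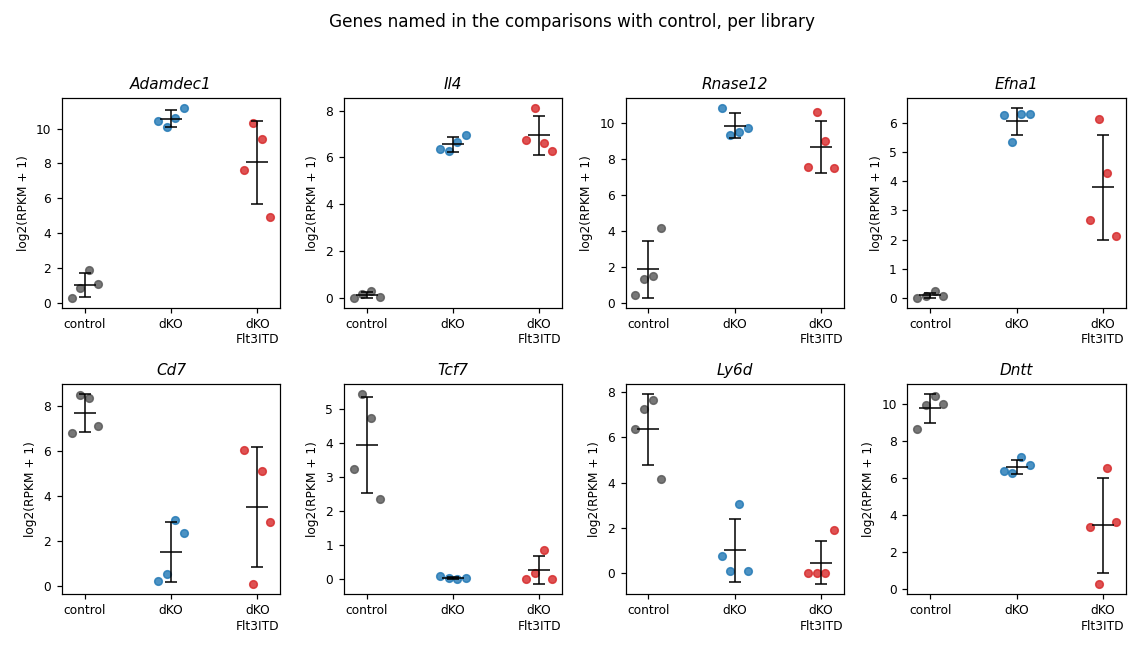
Values of log2(RPKM + 1) per library (points), with the mean and SD of each group of 4 in black, for 4 genes higher and 4 lower than in control, each called in at least 1 comparison. Dntt did not pass in dKO (adjusted p = 0.0982) and passed in dKO_Flt3ITD, and Cd7 lost its dKO_Flt3ITD call in 6 of 8 fits without 1 library.

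Limma called 160 genes, 106 up and 54 down, with 1435 at an unadjusted p under 0.05, and 820 of all tested genes, or 7.67%, had no overlap between groups, 152 of the 160 among them. Voom on the recovered reads called 32, of which 31 were among the 160. Il4, Dntt, Lck and Cox6a2 passed in both tests, while Adamdec1, Ccl5, Serpina3f, Socs2 and Fos did not pass voom, with adjusted p of 0.258, 0.265, 0.113, 0.0715 and 0.103. Rescaling to a fixed sum per library gave 83 up and 79 down, and put the median log2 fold change of all genes at −0.22, against −0.11 for dKO against control and −0.10 for dKO_Flt3ITD against dKO. Without control 1, 2, 3 or 4 the main test called 102, 99, 100 or 94 genes, without dKO_Flt3ITD 1 or 2 it called 101 or 99, and without control 1, dKO 1 and dKO_Flt3ITD 1 together it called 105.

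Of 15 lymphoid priming genes 2 fell, Dntt and Ccr9, a chemokine receptor gene of thymus homing, which went from 9.09 ± 2.87 to 0.0214 ± 0.0428 RPKM. Dntt passed voom and Ccr9 did not, with a voom adjusted p of 0.103. Adjusted over the list alone, 6 fell and 1 rose. Camera called this list down with adjusted p = 0.000189, and it was the only list called with an estimated correlation as well, at adjusted p = 0.0387. Fry gave this list and the stem and progenitor genes adjusted p = 0.000482 each. It also called the STAT5 targets, with adjusted p = 0.0323, and the cell cycle genes, with adjusted p = 0.0448, and no other list. Of 18 T-cell specification genes 2 fell, Tcf7 and Lck, and 4 when adjusted over the list alone, with camera adjusted p = 0.00488, and adjusted p = 0.144 with an estimated correlation. Lck passed voom and Tcf7 did not, with a voom adjusted p of 0.150. Of 19 stem and progenitor genes 4 rose, among them Procr, Myct1 and Hlf, and 9 rose and 3 fell when adjusted over the list alone, with camera adjusted p = 0.0164, and adjusted p = 0.144 with an estimated correlation. Hlf lost its call without control 3 or control 4, with a highest adjusted p of 0.0664 in limma. Procr, Myct1 and Hlf did not pass without control 1, dKO 1 and dKO_Flt3ITD 1 together, nor in voom.

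Of 19 STAT5 targets 4 rose, Socs2, Gimap4, Socs1 and Id1, and 1 fell. Socs1, a feedback inhibitor of cytokine signalling, rose from 0.0214 ± 0.0284 to 9.61 ± 7.55 RPKM. Id1, whose groups overlapped, was near the threshold and lost its call in 6 of 8 fits without 1 library, with a highest adjusted p of 0.138 in limma. None of these 4 passed voom. Adjusted over the list alone, 9 rose and 2 fell, with camera adjusted p = 0.00488, and adjusted p = 0.144 with an estimated correlation. Of 10 ERK output genes 1 fell, the phosphatase gene Dusp6, from 89.1 ± 34.9 to 10.5 ± 12.8 RPKM, with camera adjusted p = 0.0129 for the list, and adjusted p = 0.144 with an estimated correlation. All 20 interferon response genes had positive log2 fold changes and 1 rose, Ifi27l2a, from 137 ± 51.2 to 1955 ± 1308 RPKM. Dusp6, Id1 and Ifi27l2a did not pass without control 1, dKO 1 and dKO_Flt3ITD 1 together, and Ifi27l2a did not pass voom. Adjusted over the list alone 8 rose, with camera adjusted p = 3.11e-08, and adjusted p = 0.182 with an estimated correlation. Of 25 cell cycle genes 22 had negative log2 fold changes and none passed, with camera adjusted p = 4.06e-05, and adjusted p = 0.144 with an estimated correlation.

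Of 14 dissociation stress genes 3 fell, Fos, Jun and Zfp36, with camera adjusted p = 6.57e-07, and adjusted p = 0.175 with an estimated correlation. Jun lost its call in 4 and Zfp36 in 5 of 8 fits without 1 library, with a highest adjusted p of 0.120 and 0.0895. Among 7 macrophage genes 2 rose, Spic and Emr1, each near the threshold and lost in 7 and 6 of 8 fits without 1 library, with a highest adjusted p of 0.161 and 0.157 in limma. The macrophage list had camera adjusted p = 0.0343, 7 dendritic cell genes adjusted p = 0.0222, both upward, and 4 natural killer and innate lymphoid genes adjusted p = 0.0130 downward. With an estimated correlation these were adjusted p = 0.227, 0.318 and 0.144. Of 26 granulocyte and monocyte genes 1 rose, Ctsg, lost in 4 of 8 fits without 1 library with a highest adjusted p of 0.0975. Jun, Spic, Emr1 and Ctsg also did not pass without control 1, dKO 1 and dKO_Flt3ITD 1 together, and none of Fos, Jun, Zfp36, Spic, Emr1 and Ctsg passed voom.

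The lists that camera called in no comparison were those of Notch targets, B-lineage genes, Hox genes, granulocyte and monocyte genes, later thymocyte genes, erythroid and megakaryocyte genes, thymic stroma, Polycomb complex components, the RUNX family, genes associated with early thymic progenitor leukaemia, MYC and ribosome biogenesis, and p53 targets. Besides Ctsg, the members of these lists that passed were Tcf7 and Ly6d, down in both comparisons with control, and S1pr1, a receptor of later thymocytes, up in both. Tcf7 and Ly6d passed voom in neither, with a voom adjusted p of 0.176 for Ly6d in dKO_Flt3ITD. S1pr1 lost its call without dKO 3 or dKO 4 in the first, and in 7 of 8 fits without 1 library in the second, with a highest adjusted p of 0.0677 and 0.0785 in limma. Without control 1, dKO 1 and dKO_Flt3ITD 1 together, and in voom, S1pr1 passed in neither.

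Both comparisons with control shared 69 called genes in the same direction, 54 up and 15 down, and none in opposite directions. Independent lists of these sizes would share 0.833 up and 0.126 down. Simulated groups with no effect, set against the same controls, shared 0, but with 0.09 and 0.08 calls per comparison on average this does not show how many shared calls the controls themselves add. The fold changes of the comparisons correlated across genes with r of 0.667, against 0.50 in the simulation, and their covariance was 0.434 against 0.157. Genes are not independent replicates. The controls were also split 2 and 2, so that the group means of the comparisons shared no library. All 12 libraries still set 1 common estimate of the spread, so the call lists were not independent. The shared calls then numbered 17 to 24 over the 6 splits, r was 0.244 to 0.378 and the covariance 0.213 to 0.297. Independent lists of the sizes called in the splits would share 0.151 up and 0.0137 down on average. The simulated r of 0.50 and covariance of 0.157 hold for comparisons that share all controls, so they are no reference for the splits. With voom 5 calls were shared.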

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

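Tests in this part other than that of macrophage transcripts were chosen after the result was seen or, for mast cells and basophils, changed after it. Of 243 groups of 4 libraries, for the genes named by the rule and 4 library measures, 21 had 1 library far from the other 3. For normally spread values chance flags about 1 in 20, or 12.2. Where the other 3 libraries were listed at 0, any value above 0 was flagged, as for Ly6d, Smim5, Il3ra and Ccr9. The 21 therefore cannot be set directly against 12.2. In control, Procr was 11.3 RPKM in control 4, Spic 11.1 in control 3, Gimap4 was listed at 0 in control 1, and Cd244 was 26.5 in control 3. Control 1 also had Actr6 at 31.2 and Rrm2 at 83.9 RPKM, and control 4 had Ccnb1 at 60.7. In dKO, Efna1 was 39.7 RPKM in dKO 2, Cox6a2 2.04, Socs2 101, Igf2bp2 0.950 and Il3ra 2.31 in dKO 4, Gfi1b 3.60 in dKO 3, and Actr6 96.3 and Zfp36 15.9 in dKO 1. In dKO_Flt3ITD, Ly6d was 2.74 and Smim5 10.6 RPKM in dKO_Flt3ITD 4, both listed at 0 in the other 3, Ccr9 was 0.0855 in dKO_Flt3ITD 2, and Myct1 4.65 in dKO_Flt3ITD 3. The mean correlation of dKO_Flt3ITD 3 with the other libraries was 0.833, and the length correlation of dKO_Flt3ITD 1 was −0.384.

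Other splits of the same libraries gave far fewer called genes than both counts against control. For dKO only 1 of the 35 splits of the 8 libraries, the real one, called as many genes, 109 against at most 1 in any other. For dKO_Flt3ITD against control likewise 1 of 35 did, 160 against at most 3. A share of 1 in 35 is the smallest these splits allow, so chance is unlikely but not excluded. The same holds for genes at an unadjusted p under 0.05 in dKO_Flt3ITD against control. There 1 of 35 splits, the real one, reached 1435, the highest other being 1204. Other splits did reach the 981 in dKO against control, which 2 of 35 gave, the highest other being 1145. For the 824 in dKO_Flt3ITD against dKO 3 of 35 did, the highest other being 1071, so chance cannot be excluded for either. The count of 0 calls in dKO_Flt3ITD against dKO decides nothing, since all 35 splits reach 0 whatever the data, the highest other being 1.

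The 54 genes that rose and 15 that fell in both comparisons with control could reflect other cells in the sort. Fewer early thymic progenitors would lower their other genes too. The 30 T-cell specification and lymphoid priming genes had lower quartiles of −1.14 in dKO and −1.44 in dKO_Flt3ITD. The genes that fell had median log2 fold changes of −3.86 and −3.68. This comparison cannot decide, because the genes that fell were picked for passing downward, and low genes cannot fall as far on this scale. Macrophages stay open: none of their 7 abundant transcripts passed, and their median of 9.53 RPKM in control, 18.8 in dKO and 12.2 in dKO_Flt3ITD lay above the bound set in advance, the tenth part of the 42.6 and 43.9 of the genes that rose, while their median rise over control, compared after the values were seen, was 5.42 and 2.62 RPKM against 41.03 and 38.5, below the tenth part in dKO_Flt3ITD alone. For mast cells or basophils the form set in advance counted 3 unlisted of 7 transcripts as 0, and its medians of 0.838 and 4.04 lay below that bound. They stay open because a gene missing from the table excludes nothing, and in the form that replaced it, after the values were seen, the 4 listed transcripts had a median of at most 11.7; Cpa3, a mast cell protease gene also found in progenitors, was at 75.3, 195 and 314 RPKM in control, dKO and dKO_Flt3ITD and did not pass.

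The fall of Fos, Jun and Zfp36 in dKO_Flt3ITD may come from handling before lysis or from genotype. Handling also induces heat shock genes, whose 7 members had a median log2 fold change of −0.65, 5 of them negative and none passing, and −0.48 without the 2 that the stress list also holds. The labels give no day of sorting, so handling and genotype cannot be told apart here, and the effect of genotype itself was not tested separately.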

How the results depend on the processing

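The tests on recovered reads, pseudocounts of 0.001, 0.01, 0.03 and 0.3, the length correction and the joint removal of control 1, dKO 1 and dKO_Flt3ITD 1 were chosen after seeing the data. The dKO count against control, 109 genes, became 64 with no low-value filter, which tests more genes, 210 with array weights, 67 with pseudocount 0.001 and 45 without those 3 libraries. Voom gave 5 genes, 0 with a variance trend, 5 with library totals as library sizes and 5 with both. For dKO_Flt3ITD against control, 160 genes, the values were 91 with no filter, 76, 93 and 99 with pseudocounts 0.001, 0.01 and 0.03, and 105 without those 3 libraries. Voom gave 32, 30, 27 and 28 in the same order. The recovered reads without voom's weights, at a prior count of 0.5, gave 109 and 125 genes, so the weights and not the reads account for most of the fall under voom. Which of these tests suits libraries of 100 cells better was not tested beyond the simulation, which changed no gene barely detected in control.

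For dKO_Flt3ITD against dKO, 0 genes in the main test, the count was 3 with pseudocount 5, 5 with quantile normalization, 2 with array weights, 2 with the length trend removed, and 1 with no filter, with a mean of at least 5 RPKM, with median-of-ratios scaling, with the 8 libraries alone, without those 3 libraries, and on reads without weights at prior counts 30, 60 and 100. The overlap of 69 genes was 41 with no filter, 44 with pseudocount 0.001, 34 without those 3 libraries, 20.5 on average with the controls split, and 5, 0, 4 and 4 with voom in the order above. The cause was not tested for changes other than those with fewer libraries, more genes or no weights. Leaving out 1 library gave 58 to 95, 0 to 6 and 94 to 187 genes.

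Deviations of same-numbered libraries correlated between −0.15 and 0.13, so no clear pairing by replicate number was seen. This cannot tell whether same-numbered libraries were collected or sorted together. With a replicate block the counts were 85, 0 and 116. Directions reversed for genes that did not pass. Runx1 in dKO_Flt3ITD against dKO was −0.090 with rescaling to a fixed sum, and from −0.086 to 0.19 over the fits without 1 library. In those fits Flt3 in the same comparison ran from −0.54 to 0.47, and Rag1 in dKO_Flt3ITD against control from −0.20 to 0.58. Of the other results for named genes 2386 kept direction and side of the threshold, 194 lost the call and 36 gained it. The 2386 include many results of genes that passed in neither fit, so they do not measure how often a call held. Of the results for lists called by camera 449 kept the call and 80 lost it. Both tallies leave out the further voom forms, the reads without voom's weights and the pseudocounts chosen after seeing the data. In an RPKM table a fold depends on the pseudocount where a group has few reads, and counting error is small beside the spread between libraries.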

Other observations

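In this part voom and the tests of gene length were chosen after the data were seen. The main limma test and its fits with pseudocount 5, array weights or the 8 libraries alone were fixed in advance. Some genes that both tests called lie outside the naming rule, and were picked after their values were seen because voom called them. In dKO these were Ifitm1, Ifitm3, Serpina3g and Dtnbp1, with log2 fold changes of 2.996, 2.58, 2.54 and 1.67 in limma. Dntt, at −3.15 in voom, was the other gene of voom's 5, and did not pass the main test but passed limma with pseudocount 5, array weights or the 8 libraries alone. In dKO_Flt3ITD voom called 32 genes, 18 up and 14 down, 31 of them called by limma too. Those with a voom adjusted p from 0.00106 to 0.00924 were Dntt, Lck and 8 genes outside the rule. Of these, Ifitm1 and Ifitm3, interferon-inducible membrane protein genes, rose by 3.86 and 3.03 on the log2 scale in limma, and the class I histocompatibility genes H2-K1 and H2-D1 by 1.60 and 1.71. Serpina3g, Capg and Dtnbp1 rose by 2.54, 2.36 and 1.94, and Xrcc6 had a log2 fold change of −2.65. H2-K1 and H2-D1 are similar to each other and to other class I genes, so reads may be split between them; voom adjusted p was 0.00889 and 0.00281.

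Libraries differed in how level depended on gene length. In dKO_Flt3ITD 1 the Spearman correlation of deviation with length was −0.38, and in control 1 it was 0.26. Of the 106 genes called up in dKO_Flt3ITD against control, 58 lay in the shortest of 3 equal classes of gene length and 16 in the longest. A gene-length trend of the libraries is a candidate cause. With each library's trend removed, 147 of the 160 called genes were still called, and their median absolute log2 fold change moved from 2.91 to 2.86. Most of these calls therefore did not depend on the trend. That fit called 191 genes, 106 up and 85 down, against 106 up and 54 down in the main test. The split by length class was not computed again after the removal. These values therefore cannot decide whether the trend caused the excess of short genes.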
